A study of Mus musculus with 12 samples.

How the data were processed

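RNA was sequenced from nephron progenitor cells of 12 mouse litters, 4 in each of 3 maternal arms. Per the labels, outbred CD1 females were mated with males carrying a Six2-EGFP/Cre transgene, which marks the self-renewing cap mesenchyme of the fetal kidney, and were kept on a control diet, a control diet supplemented with the ketone body β-hydroxybutyrate, or a ketogenic diet until embryonic day 17.5. Kidneys of a whole litter were digested with collagenase and dispase, GFP-positive cells were sorted and pooled, and RNA of 50000 to 100000 cells went into a stranded total RNA kit with single reads of 100 cycles, so each library is 1 litter and litters are the replicates. The labels also describe a calorie-restricted diet, which none of these 12 libraries is said to have received.

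The arms are called normal, K and BHB after the titles and descriptions of the libraries. The labels contradict each other on the treated arms: the 4 libraries titled as ketogenic carry the supplemented diet in their treatment field, and the 4 titled as β-hydroxybutyrate carry the ketogenic diet. The labels do not settle which arm received which regimen, and expression values were not used to decide it. The contrast of both treated arms with normal, and the test for any difference among the 3 arms, do not depend on the answer.

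The authors deposited 1 table with raw counts per gene and with counts divided by 1 size factor per library. The deposited counts are whole numbers per Ensembl gene, and per the submitters' processing notes the tools were cutadapt 2.10, TopHat2 2.1.1, HTSeq 2.01 and DESeq2 1.36.0, listed without role or order. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so no coordinates are printed, and reads of overlapping antisense genes could not be told apart. The normalized signal that the authors deposited equals the count over a DESeq2 size factor: recomputed factors differed from the deposited ones by a relative 6.7e-16 at most. That column is filled for the 27370 genes whose counts sum to at least 10 over the 12 libraries, and it entered no test. The table has 55414 gene entries, of which 6250 have blank counts, among them 24 mitochondrial tRNA and rRNA genes; the other 49164 were used. A symbol was missing or shared between entries for 757 of these, which were kept under their own identifiers. No column of per-sample values was left unmapped.

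Counts as deposited were analysed in R 4.3.3. Genes were kept by edgeR's filterByExpr with its default settings (a count of about 10 in the smallest group and a total of 15), which left 17697 genes. TMM factors were computed with edgeR 4.0.16, and the main test was edgeR's robust quasi-likelihood test on all 12 libraries in 1 model with a mean per arm, which leaves 9 residual degrees of freedom. Benjamini-Hochberg adjusted p-values at or under 0.05 counted as past the threshold. The comparisons were K with normal, BHB with normal, K with BHB (which also tests whether both arms' differences from normal differ), both treated arms with normal, and any difference among the 3 arms. Levels are TMM-scaled CPM (the count relative to the scaled library size), and log2 CPM for list means used a prior count of 2.

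A set of 36 gene lists was fixed before the data were examined. They cover nephron progenitor self-renewal, early nephron differentiation, proximal tubule, distal tubule and loop of Henle, podocyte, stroma, ureteric epithelium, endothelium, myeloid and other leukocytes, erythroid cells, ketone body metabolism, fatty acid oxidation with PPAR targets, glycolysis, the tricarboxylic acid cycle, nuclear and mitochondrially encoded oxidative phosphorylation, cholesterol and fatty acid synthesis, ATF4 targets, endoplasmic reticulum chaperones, insulin and mTOR signalling, imprinted growth genes, G2 and M phase, DNA replication, p53, hypoxia, oxidative stress, Wnt, FGF, BMP and TGF-beta targets, histone deacetylases and sirtuins, dissociation stress, interferon response, sex chromosome markers, cytosolic ribosomal proteins and replication-dependent histones. Lists were tested on limma 3.58.1 voom values with camera at a preset correlation of 0.01, again with the correlation estimated, and with fry, each adjusted over the 36 lists of a comparison. Camera compares a list with all other genes, while fry tests whether its genes move one way on balance or, in its mixed form, change in either direction. List counts are given after adjustment over all genes and adjusted over the list alone. The list mean per library was also compared by a two-sided exact permutation test, in which 4 libraries against 4 cannot give a p under 0.0286. Wt1 stands in both the podocyte and the progenitor lists, and Cdkn1c and Dlk1 stand in a marker list and in the imprinted list.

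The rule for named genes was fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls among genes past the threshold. Where no gene passes in a direction, as was so in every comparison, it takes the 5 genes with the smallest p in that direction, with a mean log2 CPM of at least 1 and without predicted-gene symbols, and gives them as values. It adds up to 2 members by smallest p of each list described, and always Six2, Cited1, Eya1, Wnt4, Lhx1, Oxct1, Bdh1, Cpt1a and Pdk4. Some genes that the rule takes are not reported here. Any other gene named is said to have been chosen after its values were seen.

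Alternatives fixed before the data were examined were DESeq2 1.42.0, limma voom with sample quality weights, size factors (RLE) or upper-quartile scaling in place of TMM, no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, the replicate number as a block, a model of only the compared arms, and each library left out in turn. Chosen after seeing the data were leaving out K 3, K 4, BHB 1 and BHB 2, which have the most RNA of non-progenitor markers, a non-progenitor marker score as a covariate, K and normal alone paired by replicate number, the exact test of list means, and the count of genes whose libraries of 2 arms do not overlap. That score is the mean of the 6 lists for proximal tubule, distal tubule, podocyte, ureteric epithelium, endothelium and myeloid cells. Both fold change sets share the 4 normal libraries, so their similarity was set beside 100 simulated data sets without an effect, and DESeq2's overlap of calls beside 40. Deviations of same-numbered K and normal libraries from their arm means correlated across genes at 0.114 to 0.461, over 0.1 in 4 of 4 pairs, which was taken as pairing by number for this comparison. It rests on the values alone: what a shared number stands for is not given in the sources used here, and each library is its own litter. Numbers 2, 1, 4 and 3 also stood in that order of rising marker score in both arms. In normal the scores were 2.15, 2.85, 2.92 and 3.28, and in K 3.21, 3.59, 5.10 and 5.27. Pairing by number thus cannot be told apart from pairing by rank of that score. The fit of all 12 libraries and the exact tests ignore the number; a paired exact test of 4 pairs cannot give a p under 0.125.

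Tests were tried on counts simulated for all 12 libraries from the real means, library sizes and dispersions, with known changes put into the K libraries and 17407 genes left to test in K with normal. At a 2-fold change, edgeR's quasi-likelihood test recovered 54.1% of 98 changed genes, DESeq2 70.4% and limma voom 51.0%. At a 4-fold change these shares were 85.4%, 93.8% and 85.4% of 96 genes. Among unchanged genes edgeR called 8, DESeq2 30 and limma voom 10. Camera and fry gave p-values of 3.21e-15 and 4.75e-07 for a simulated shifted list, and 0.11 and 0.122 for an unshifted list. Simulated genes were drawn independently of each other, while genes of the real lists are correlated (estimated at 0.935 for distal tubule in K with normal). This trial therefore cannot tell whether camera's preset correlation holds for the real lists. The shares recovered and the unchanged genes called may likewise differ in the real libraries, so 0 calls there do not exclude changes of this size.

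Libraries held 7532784 to 12276119 counts, so 1 CPM stands for about 8 to 12 counts per library and genes near or below that level rest on few counts. No libraries of the same arm were duplicates: a chi-square test of their counts gave 4.22 to 44.9 per degree of freedom. Pearson's r of log2 CPM between any 2 libraries, across genes, ran from 0.922 to 0.987.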

Results

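Sorted Six2-GFP-positive nephron progenitors of 12 fetal mouse litters were profiled by RNA sequencing, with 4 litters in each of the normal, K and BHB arms. The series addresses what maternal ketosis does to the fetal kidney, whose cap mesenchyme holds the Six2-positive cells that renew themselves and form nephrons. Total counts were 10798665, 10485174, 11404335 and 8292620 for normal 1 to 4. They were 10012462, 10728338, 9651130 and 9735508 for K 1 to 4, and 11537733, 9698385, 12276119 and 7532784 for BHB 1 to 4. After filtering, 17697 genes were tested. Levels are mean CPM ± SD over the litters of an arm (n = 4), and fold changes are on the log2 scale ± SE unless written as a fold. Because the labels give opposite accounts of which treated arm received which regimen, K and BHB are names of library sets here and not of diets.

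All 12 libraries had the transcripts of the sorted population, but they differed in the level of markers of other kidney and blood cells. The self-renewal list had a mean log2 CPM of 7.16 ± 0.04 in normal, 6.79 ± 0.35 in K and 6.87 ± 0.28 in BHB (two-sided exact permutation p = 0.0857 for each treated arm against normal). The non-progenitor marker score, a mean over tubule, podocyte, ureteric, endothelial and leukocyte lists, was 2.80 ± 0.47 in normal, 4.29 ± 1.04 in K and 4.08 ± 0.67 in BHB. The exact p was 0.0571 for K and 0.0286 for BHB against normal, 0.154 for each after adjustment over 9 tests chosen after seeing the data, and 0.743 for K against BHB. It was highest in K 3 (5.27), K 4 (5.10), BHB 1 (4.93) and BHB 2 (4.29), against 2.15 to 3.28 in the normal libraries and 3.21 to 3.60 in the other treated ones. The share of the nuclear RNA Malat1, chosen after its values were seen, was also highest in those 4 libraries (2.43% in K 4, 2.22% in K 3, 2.02% in BHB 2 and 2.00% in BHB 1), against 1.47% to 1.94% in the others. By arm it was 1.61% ± 0.159 in normal, 2.097% ± 0.288 in K (exact p = 0.0571) and 1.82% ± 0.224 in BHB (exact p = 0.171). Slc12a1, the salt cotransporter of the loop of Henle, averaged 234 ± 132 CPM in normal, 987 ± 783 in K and 637 ± 530 in BHB, and the endothelial cadherin Cdh5 2.81 ± 1.73, 20.9 ± 11.6 and 20.9 ± 25.2. Both genes were chosen after their values were seen. The first principal component of all genes took 50.1% of the variance and placed K 3 (73.0), K 4 (63.8), BHB 1 (54.5) and BHB 2 (20.98) apart from the other libraries (-58.9 to -11.0). The share of mitochondrial transcripts was 0.985% ± 0.238 in normal, 1.31% ± 0.145 in K and 1.05% ± 0.134 in BHB, with an exact p of 0.143 for K against normal, 0.714 for BHB against normal and 0.0571 for K against BHB. Total counts, the share of the 100 most abundant genes, ribosomal protein transcripts and haemoglobin transcripts gave exact p-values from 0.143 to 1, and the smallest adjusted p over these 15 tests was 0.536.

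**Figure D1:**
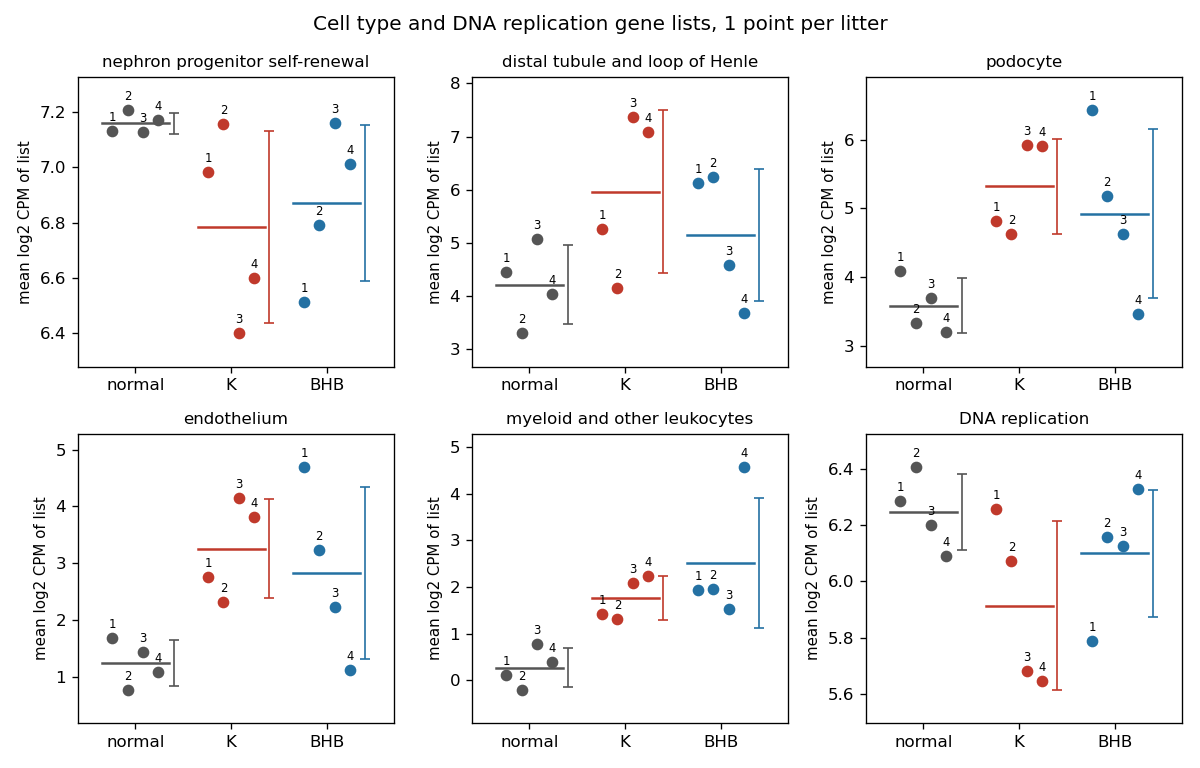
Mean log2 CPM of 6 gene lists in each litter, by arm, with digits for the replicate number, a line for the arm mean and a bar for the SD. The self-renewal list averaged 7.16 in normal, 6.79 in K and 6.87 in BHB, and the endothelial list 1.24, 3.26 and 2.83.

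K was compared with normal to ask what 1 of the treated regimens did to progenitors. Genes of fatty acid oxidation, ketone body metabolism and mitochondrial respiration were higher in the K litters, and genes of fatty acid synthesis, DNA replication and progenitor self-renewal were lower. These are camera's calls at a preset correlation, and with an estimated correlation none of these lists was called (adjusted p from 0.257 to 0.554). Marker lists of other cell types were higher in the same arm, and without K 3, K 4, BHB 1 and BHB 2 the median of nuclear oxidative phosphorylation genes went from 0.34 to -0.06. Cited1 (ENSMUSG00000051159), a marker of the least committed cap mesenchyme, was at 12.6 ± 3.36 CPM in K and 23.9 ± 0.94 in normal. No single gene passed edgeR's quasi-likelihood test after adjustment (smallest adjusted p = 0.103), while 391 did with K and normal paired by replicate number, so single-gene differences are given as values.

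The fatty acid oxidation and PPAR target list stood above other genes in K (camera adjusted p = 9.67e-08; adjusted p = 0.48 with an estimated correlation), with 19 of 20 members higher, 0 called over all genes and 14 adjusted over the list alone. Cpt1a (ENSMUSG00000024900), which admits fatty acids to mitochondria, was at 186 ± 87.9 CPM against 72.7 ± 8.28 (1.358 ± 0.314). Pdk4 (ENSMUSG00000019577), the kinase that shuts off pyruvate dehydrogenase, was at 80.9 ± 43.2 against 17.3 ± 3.28 (2.22 ± 0.63). The PPAR targets Cyp4a10 and Angptl4 were at 8.50 ± 7.98 and 19.7 ± 14.2 CPM against 0.62 ± 0.44 and 4.59 ± 0.99. Angptl4 was chosen after its values were seen. Every K litter exceeded every normal litter for Cpt1a, Pdk4, Cyp4a10 and Angptl4. The list's median of 0.85 was 0.12 with K 3, K 4, BHB 1 and BHB 2 left out, where camera at the preset correlation still called it (adjusted p = 9.05e-05). With the marker score as a covariate the median was -0.10 and the list was not called (0.681). Cpt1a, Pdk4, Cyp4a10 and Angptl4 were at 0.34, 0.45, 1.43 and 0.41 with the covariate.

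Ketone body genes as a list were higher in K (camera adjusted p = 0.0407; adjusted p = 0.48 with an estimated correlation), with 8 of 10 higher, 0 called over all genes and 4 adjusted over the list alone. That call was lost without normal 1, normal 2, normal 3, K 3 or K 4 (adjusted p from 0.056 to 0.0827). Oxct1 and Bdh1, the enzymes that use ketone bodies, were at 244 ± 91.6 and 40.3 ± 30.9 CPM in K and 191 ± 20.9 and 17.8 ± 5.02 in normal, with overlapping litters. With the 4 libraries left out, their log2 differences were -0.17 and -0.39. Aacs, which activates ketone bodies for lipid synthesis, was at 31.3 ± 6.61 CPM against 44.0 ± 2.80 (-0.49 ± 0.14). Fatty acid synthesis genes were lower in K (camera adjusted p = 4.4e-05; adjusted p = 0.257 with an estimated correlation), with 10 of 12 lower, 0 called over all genes and 7 adjusted over the list alone. This was the only list that fry called for a shift in one direction (adjusted p = 0.00778, and 0.0649 with K and normal paired). The stearoyl-CoA desaturases Scd1 (ENSMUSG00000037071) and Scd2 were at 5.43 ± 2.32 and 574 ± 46.8 CPM in K against 11.4 ± 1.35 and 794 ± 74.3 in normal, with no overlap between litters. Scd1 differed by -1.07 ± 0.27 in all litters, and by -1.58 with the 4 libraries left out (adjusted p = 0.0182, against 0.00859 to 0.508 over all alternatives). The list's median of -0.31 was -0.20 without those libraries and -0.12 with the covariate. Cholesterol synthesis genes were not called (camera adjusted p = 0.205; 8 higher and 12 lower).

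All 13 mitochondrially encoded genes were higher in K (camera adjusted p = 2.93e-07; adjusted p = 0.48 with an estimated correlation), with 0 called over all genes and 6 adjusted over the list alone, and fry's mixed test called the list (adjusted p = 0.0115). The complex I subunits mt-Nd6 (ENSMUSG00000064368) and mt-Nd2 (ENSMUSG00000064345) were at 366 ± 41.3 and 1016 ± 40.8 CPM against 168 ± 34.5 and 726.5 ± 123. mt-Nd6 had the smallest p of all genes (1.13 ± 0.15; edgeR adjusted p = 0.103, and 0.015 without normal 4). It lies on the opposite strand to most mitochondrial genes, and the strand setting of the counting is not given in the sources used here. The list's median was 0.38, or 0.32 without the 4 libraries and 0.16 with the covariate. Nuclear genes of oxidative phosphorylation (32 of 32 higher, 0 adjusted over the list alone; camera adjusted p = 9.08e-07) and of the tricarboxylic acid cycle (20 of 20 higher, 0 adjusted over the list alone; camera adjusted p = 1.91e-06) also stood above other genes; with an estimated correlation these gave an adjusted p of 0.554 and 0.506. Pdha1 and Idh2 were at 182 ± 53.7 and 366 ± 114 CPM against 128 ± 5.58 and 257 ± 17.8. Without K 3, K 4, BHB 1 and BHB 2 the medians of both lists changed sign, from 0.34 to -0.06 and from 0.35 to -0.01.

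Glycolysis and glucose uptake genes (15 of 17 higher; 3 adjusted over the list alone; camera adjusted p = 4.86e-06) and hypoxia targets (11 of 12 higher; 4 adjusted over the list alone; camera adjusted p = 7.08e-05) were higher in K. Both gave adjusted p = 0.48 with an estimated correlation, and neither list had a gene called over all genes. The glucose transporter Slc2a1 and the glycolytic enzyme Gpi1 were at 165 ± 35 and 386 ± 51.7 CPM against 95.3 ± 6.78 and 293 ± 24.4. The mitophagy receptor Bnip3 and the angiogenic factor Vegfa were at 62.1 ± 12.4 and 363 ± 37.4 against 30.6 ± 9.70 and 261 ± 28.3, and all 4 genes separated the arms. The medians of these lists were 0.40 and 0.60, and 0.26 and 0.41 without the 4 libraries (camera adjusted p = 1.79e-07 and 9.75e-07). With the covariate they were 0.08 and 0.12, and neither list was called (adjusted p = 0.132 and 0.094). Oxidative stress genes (14 of 16 higher, 0 adjusted over the list alone; camera adjusted p = 0.00629; adjusted p = 0.587 with an estimated correlation) had a median of 0.35, and of -0.01 without those libraries; the call was also lost without K 3 (adjusted p = 0.072). Dissociation stress genes (14 of 16 higher, 1 adjusted over the list alone; camera adjusted p = 0.000778; adjusted p = 0.506 with an estimated correlation) included the immediate-early phosphatase Dusp1 at 145 ± 24.7 CPM against 73.6 ± 6.19. Such genes respond to enzymatic tissue digestion, which all libraries went through. Their median of 0.40 was 0.42 without the 4 libraries (camera adjusted p = 3.36e-08) and 0.27 with the covariate (0.00464). Nupr1, a stress-responsive chromatin protein, was at 3.85 ± 1.75 CPM against 0.367 ± 0.152, in an ATF4 target list that was not called (camera adjusted p = 0.395).

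Nephron progenitor self-renewal genes were lower in K (camera adjusted p = 1.23e-05; adjusted p = 0.48 with an estimated correlation), with 15 of 16 lower, 0 called over all genes and 1 adjusted over the list alone. Six2 (ENSMUSG00000024134) was at 324 ± 104 CPM against 445 ± 54.7 (-0.46 ± 0.23) and Eya1 at 443 ± 136 against 600 ± 47.7 (-0.44 ± 0.19), both with overlapping litters. Cited1 and Hoxd11 (94.9 ± 16.6 against 121 ± 3.69 CPM) were lower in every K litter than in any normal one. The list's median of -0.37 was -0.10 without the 4 libraries (camera adjusted p = 0.0254). With the marker score as a covariate it was 0.04 (0.0816), with Six2 at 0.14 and Cited1 at -0.44. All 20 DNA replication genes were lower (camera adjusted p = 9.08e-07; adjusted p = 0.48 with an estimated correlation), with 0 adjusted over the list alone. The helicase subunits Mcm2 and Mcm6 were at 153 ± 30.5 and 220 ± 40.5 CPM against 207 ± 19.7 and 280 ± 29.0. The replication list's median was -0.32, or -0.09 without the 4 libraries (camera adjusted p = 0.0254) and 0.05 with the covariate (0.132). Genes of G2 and M phase had a median of 0.025 (camera adjusted p = 0.815). Early nephron differentiation genes were higher (15 of 20, 9 adjusted over the list alone; camera adjusted p = 0.0033; adjusted p = 0.48 with an estimated correlation). Among them Lhx1, which patterns the renal vesicle, was at 29.3 ± 8.02 against 18.0 ± 2.86 CPM (0.70 ± 0.25), Clec18a at 49.2 ± 26.4 against 21.4 ± 4.73 and the Notch ligand Jag1 at 121 ± 34.4 against 79.4 ± 7.67. Wnt4, which drives the mesenchyme to epithelium, was at 119 ± 33.6 against 144 ± 26.3 (-0.27 ± 0.24).

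Markers of differentiated and non-renal cells were also higher in K. This held for lists of distal tubule and loop of Henle (10 of 10 higher, 7 adjusted over the list alone; camera adjusted p = 0.000144), podocyte (11 of 12, 10; 1.23e-05), endothelium (12 of 12, 11; 6.37e-06) and leukocytes (10 of 10, 0; 0.00128), each with an adjusted p of 0.48 with an estimated correlation. Slc12a3 and Tmem52b, both distal, were at 351 ± 282 and 123 ± 98.4 CPM against 59.4 ± 44.9 and 25.9 ± 10.2. The endothelial junction proteins Cldn5 and Esam were at 8.16 ± 4.95 and 6.59 ± 2.99 against 2.34 ± 0.70 and 1.66 ± 0.40. The complement gene C1qb and the macrophage receptor Csf1r were at 1.75 ± 0.45 and 9.61 ± 6.62 against 0.216 ± 0.16 and 2.88 ± 1.30. Proximal tubule (camera adjusted p = 0.00488) and ureteric lists (0.00891) were called as well (14 of 15 and 11 of 11 higher), with 0 genes adjusted over the list alone; with an estimated correlation these gave an adjusted p of 0.612 and 0.592. The proximal call was lost without normal 2, K 3 or K 4 (adjusted p = 0.158, 0.0695 and 0.0718) and the ureteric call without K 3 (0.0945). Interferon response genes (7 of 7 higher; camera adjusted p = 0.0125; adjusted p = 0.48 with an estimated correlation) and cytosolic ribosomal protein genes (72 of 81 lower; camera adjusted p = 0.000378; adjusted p = 0.69 with an estimated correlation) moved with the same libraries: medians of 1.31 and -0.10 were 0.49 and 0.07 without them, and the ribosomal call was lost without K 4 (0.582). Without the 4 libraries the early nephron median went from 0.65 to 0.19, the distal from 2.19 to 0.485, the podocyte from 1.93 to 1.045, the endothelial from 2.36 to 1.45, the leukocyte from 1.81 to 1.24, the proximal from 1.29 to -0.71 and the ureteric from 1.21 to -0.003. Camera still called the distal and leukocyte (adjusted p = 0.0254 each), podocyte and endothelial (9.7e-11 each) and interferon lists (0.0093) there. It did not call the early nephron, proximal and ureteric lists (0.0524, 0.215 and 0.93). With the covariate the early nephron, podocyte, endothelial and interferon medians were 0.03, 0.295, 0.35 and 0.08, and none of these lists was called (adjusted p from 0.144 to 0.89). The leukocyte median was 2.19 with the covariate and stayed called (0.000286). The proximal, distal, podocyte, ureteric, endothelial and leukocyte lists form the marker score, by which the 4 libraries also rank highest. A fall of these lists under either setting was therefore partly built in and decides nothing about its cause.

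The remaining lists were not called by camera in K against normal. Adjusted p was 0.0622 for BMP and TGF-beta targets, 0.135 for stroma (0.00429 with K and normal paired), 0.317 for insulin and mTOR signalling and 0.395 for imprinted growth genes and for replication-dependent histones. It was 0.404 for Wnt targets, 0.415 for endoplasmic reticulum chaperones and for histone deacetylases and sirtuins, 0.464 for FGF targets, 0.49 for p53 targets and 0.531 for sex chromosome markers. The p53 list passed fry's mixed test (adjusted p = 0.0414), which calls change in either direction, with 8 members higher and 8 lower.

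Among single genes that are not members of these lists, the smallest p belonged to Igdcc3 (ENSMUSG00000032394), an immunoglobulin-domain membrane protein, at 12.9 ± 2.45 CPM in K against 27.7 ± 0.40 in normal (-1.11 ± 0.16; edgeR adjusted p = 0.115). Fnip1, a folliculin-binding partner of AMP-activated kinase, was at 82.9 ± 3.70 against 56.5 ± 3.74 (0.55 ± 0.11), and the branched-chain ketoacid dehydrogenase phosphatase Ppm1k at 28.7 ± 1.53 against 20.7 ± 0.99. Arl6ip1 was at 56.1 ± 6.54 against 38.9 ± 2.54, and the ectonucleotidase Entpd1 at 2.25 ± 0.88 against 0.343 ± 0.175. Lower in K were the co-chaperone Dnajb5 (9.66 ± 0.44 against 16.0 ± 1.99 CPM), the transcription factor Sox13 (60.4 ± 4.72 against 85.4 ± 3.16) and the microtubule-associated Map1a (24.7 ± 1.80 against 34.7 ± 4.44). edgeR's adjusted p was 0.221 for each of these genes except Igdcc3, and none of their litters overlapped between arms. They were taken by smallest p in this comparison, so the lack of overlap was partly built in. Which cells their RNA came from was not tested.

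For K against normal, edgeR's quasi-likelihood test called 0 genes, with 3502 at unadjusted p under 0.05 (2142 higher and 1360 lower) where 885 were expected. DESeq2 called 276 (207 higher and 69 lower) and limma voom 2 (mt-Nd6 and Igdcc3). With K 3, K 4, BHB 1 and BHB 2 left out, edgeR called 12 (10 higher and 2 lower), among them Cpt1a (0.65; adjusted p = 0.0263), whose adjusted p over all alternatives ran from 0.00588 to 0.7. Without normal 4 it called 1, mt-Nd6. With only these arms, paired by replicate number, it called 391 (345 higher and 46 lower; 4087 at unadjusted p under 0.05), against 0 with only these arms and no pairing. Of the 43 genes named for this comparison 21 passed there (edgeR adjusted p from 0.0116 to 0.0493), among them mt-Nd6, Cyp4a10, Igdcc3, Cited1, Pdk4, Scd1 and Cpt1a, while Six2 did not (0.0662). Camera then called 22 lists in place of 21, and 0 with an estimated correlation (smallest adjusted p = 0.428). Fry called 4 in place of 1: stroma (adjusted p = 0.00172), leukocytes (0.00986), mitochondrially encoded genes (0.0326) and interferon response (0.0326), and its mixed test 16 in place of 3. Arms did not overlap at all for 1792 genes, or 10.1%, where chance gives 2.86% on average. Genes are not independent and this count was not tried on other splits of the litters, so it does not exclude chance.

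**Figure D2:**
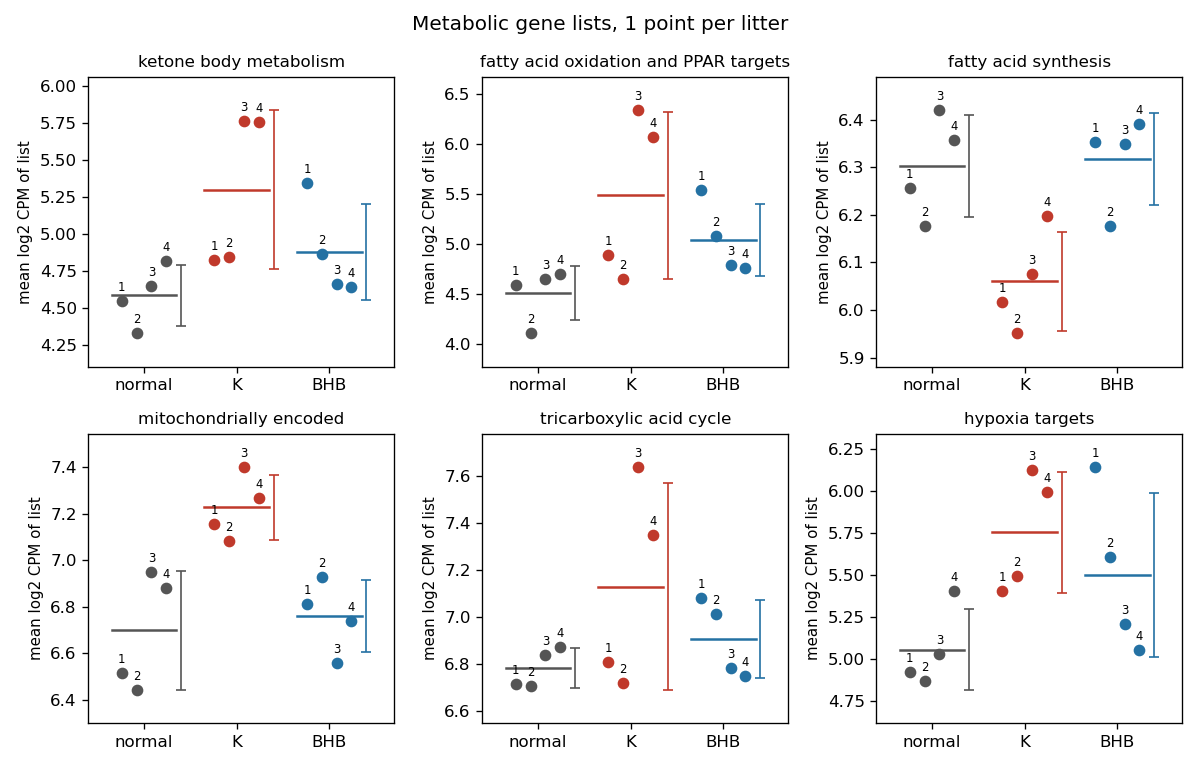
Mean log2 CPM of 6 metabolic gene lists in each litter, by arm, with digits for the replicate number, a line for the arm mean and a bar for the SD. The fatty acid oxidation list averaged 4.51 in normal, 5.49 in K and 5.04 in BHB, with K 3 (6.34) and K 4 (6.07) highest, and the mitochondrially encoded list 6.70, 7.23 and 6.76.

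BHB was compared with normal to ask the same of the other treated regimen. Leukocyte, endothelial and podocyte markers were higher in BHB, while self-renewal and ribosomal protein genes were lower. With an estimated correlation none of these 5 lists was called (adjusted p = 0.77 for each), and with the marker score as a covariate the self-renewal and ribosomal medians were 0.11 and 0.09, above 0. The myeloid lysozyme Lyz2 was at 10.4 ± 12.8 CPM against 0.529 ± 0.244 in normal, a 19.3-fold difference, and Cldn5 at 9.66 ± 4.07 against 2.34 ± 0.70. Without BHB 4 the log2 difference of Lyz2 was 2.92, against 4.27 with it. Cited1 was at 15.3 ± 4.01 against 23.9 ± 0.94 and was lower in every BHB litter than in any normal one. No gene passed edgeR's test (smallest adjusted p = 0.309).

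Leukocyte genes were higher in BHB (10 of 10, 9 adjusted over the list alone; camera adjusted p = 6.69e-06), as were endothelial (12 of 12, 11; 3.38e-05) and podocyte genes (11 of 12, 10; 3.77e-05). With an estimated correlation each had an adjusted p of 0.77. C1qb was at 3.88 ± 5.38 CPM against 0.216 ± 0.16 and Esam at 6.31 ± 5.67 against 1.66 ± 0.40. The calprotectin subunit S100a9, chosen after its values were seen, was at 34.7 CPM in BHB 4, 8.19 in BHB 1 and 1.46 to 1.52 in BHB 2 and BHB 3, against at most 0.294 in normal. Lyz2 was likewise highest in BHB 4, at 29.5 CPM. Stroma (11 of 12 higher, 0 adjusted over the list alone; camera adjusted p = 0.0153), proximal tubule (14 of 15, 0; 0.000929), distal tubule (10 of 10, 0; 0.0191) and early nephron differentiation lists (18 of 20, 0; 0.00296) were higher too, each with adjusted p = 0.77 with an estimated correlation. The stroma call was lost without BHB 1 (0.805), the proximal call without normal 2 (0.0684), and the distal call without normal 2, BHB 1 or BHB 2 (0.0886, 0.145 and 0.135). The ureteric list was not called (0.103), nor was the erythroid list in BHB (0.283) or in K (0.737). Without K 3, K 4, BHB 1 and BHB 2 the leukocyte median went from 3.18 to 3.99, the endothelial from 2.32 to 0.60, the podocyte from 1.77 to 0.55 and the distal from 1.25 to -0.22. Camera still called the leukocyte, endothelial and podocyte lists there (adjusted p = 9.2e-07, 0.0132 and 0.00175). It also called the early nephron and proximal lists (0.000664 and 9.6e-09), but not the distal and stroma lists (0.907 and 0.507). The BHB arm was then only BHB 3 and BHB 4, with leukocyte list means of 1.54 and 4.58 (log2 CPM), so the 3.99 leans on BHB 4. The stroma median of 0.74 was 0.05 without K 3, K 4, BHB 1 and BHB 2 and 0.15 with the covariate, and the early nephron median of 0.605 was 0.32 and 0.08. The covariate left the endothelial median at 0.51 (camera adjusted p = 0.0668) and the podocyte median at 0.27 (0.0385), while the leukocyte median was 3.60 (4.28e-06). These lists and the tubule lists are part of the marker score, so a fall under either setting was partly built in.

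Self-renewal genes were lower in BHB (14 of 16, 0 adjusted over the list alone; camera adjusted p = 0.000517; adjusted p = 0.77 with an estimated correlation). The homeobox gene Meox1 was at 18.6 ± 4.84 CPM against 32.9 ± 3.99, Six2 at 325 ± 86.7 (-0.46 ± 0.23), Eya1 at 490 ± 71.7 (-0.29 ± 0.19), Wnt4 at 133 ± 35.4 (-0.11 ± 0.24) and Lhx1 at 29.4 ± 9.88 (0.70 ± 0.25). The list's median of -0.26 was -0.11 without the 4 libraries and 0.11 with the marker covariate. Cytosolic ribosomal protein genes (74 of 81 lower, 0 adjusted over the list alone; camera adjusted p = 6.69e-06) included Rpl15 at 212 ± 17.9 against 263 ± 19.8 CPM and Rpl7 at 785 ± 71.5 against 925 ± 89.7. DNA replication genes were lower (19 of 20, 0 adjusted over the list alone; 0.00568), a call lost without normal 2 or BHB 1 (0.0684 and 0.358). Both lists gave adjusted p = 0.77 with an estimated correlation, and their medians of -0.14 and -0.17 were -0.05 and -0.055 without the 4 libraries and 0.09 and 0.18 with the covariate.

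Fatty acid oxidation and PPAR targets were higher in BHB (19 of 20, 0 adjusted over the list alone; camera adjusted p = 0.000761; adjusted p = 0.77 with an estimated correlation). Their median was 0.48, or 0.21 without the 4 libraries (camera adjusted p = 0.00634) and -0.36 with the covariate (3.45e-06). Cpt1a was at 111 ± 31.4 CPM (0.61 ± 0.31), above every normal litter, and the lipid droplet protein Plin2 at 24.6 ± 7.63 against 16.3 ± 2.37. Pdk4 was at 59.0 ± 56.5 (1.77 ± 0.63), with 140 CPM in BHB 1. Ketone body genes as a list were not called (0.624); Oxct1 was at 211 ± 31.0 (0.15 ± 0.22) and Bdh1 at 35.7 ± 22.0 (1.01 ± 0.62). Fatty acid synthesis (0.361), mitochondrially encoded (0.478), tricarboxylic acid cycle (0.103) and cholesterol synthesis genes (0.0565) were not called, and Scd1 was at 13.7 ± 3.33 CPM against 11.4 ± 1.35, a gene chosen here after its values were seen. Nuclear oxidative phosphorylation genes (30 of 32 higher, 0 adjusted over the list alone; camera adjusted p = 0.0149; adjusted p = 0.776 with an estimated correlation) lost the call without normal 1 or BHB 1 (0.0509 and 0.184), and their median of 0.13 was 0.02 without the 4 libraries and -0.28 with the covariate. Glycolysis genes (15 of 17 higher, 0 adjusted over the list alone; camera adjusted p = 0.000599; adjusted p = 0.77 with an estimated correlation) included Slc2a3 at 3.63 ± 1.41 against 1.92 ± 0.45 CPM and Slc2a1 at 148 ± 59.0 against 95.3 ± 6.78. That median of 0.235 was 0.05 without the 4 libraries and 0.04 with the covariate, and neither setting kept the call (camera adjusted p = 0.325 and 0.709).

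Oxidative stress genes were higher in BHB (15 of 16, 0 adjusted over the list alone; camera adjusted p = 0.00195; adjusted p = 0.77 with an estimated correlation). Heme oxygenase Hmox1 was at 39.5 ± 24.9 CPM against 9.59 ± 2.33 and the metallothionein Mt1 at 73.3 ± 57.7 against 23.1 ± 5.38. Hypoxia targets (12 of 12 higher; 0.00495) and interferon genes (7 of 7 higher; 0.0417) were called by camera with 0 genes adjusted over the list alone, each with adjusted p = 0.77 with an estimated correlation. The hypoxia call was lost without BHB 1 (0.101) and the interferon call without normal 1, normal 2, normal 4 or BHB 1 (0.0553 to 0.273). ATF4 targets (0.478) and BMP and TGF-beta targets (0.432) were not called, though Nupr1 was at 3.64 ± 4.13 CPM against 0.367 ± 0.152 and the cystine transporter Slc7a11, also of the ATF4 list, at 3.89 ± 3.73 against 0.879 ± 0.384. Medians of the oxidative stress, hypoxia and interferon lists were 0.26, 0.35 and 1.14, and 0.11, 0.05 and 0.26 without the 4 libraries (camera adjusted p = 0.0297, 0.79 and 0.118). With the covariate they were -0.095, 0.04 and 0.20, and none was called (camera adjusted p from 0.137 to 0.99).

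Genes with the smallest p included Entpd1 at 3.25 ± 1.82 CPM against 0.343 ± 0.175 (3.18 ± 0.53; edgeR adjusted p = 0.309) and the axonemal dynein Dnah5 (ENSMUSG00000022262) at 9.38 ± 1.70 against 18.9 ± 1.90 (-1.01 ± 0.16; 0.309). The synaptotagmin Syt14 was at 19.5 ± 1.15 against 28.8 ± 3.02 (-0.56 ± 0.09; 0.309). Higher with an adjusted p of 0.417 were the myelin protein Pmp22 (8.49 ± 2.21 against 4.11 ± 0.55 CPM), Ildr2 (13.9 ± 5.29 against 4.32 ± 0.69) and Dpysl5 (5.77 ± 1.60 against 2.75 ± 0.36). Lower were Eef1e1 (16.5 ± 0.65 against 21.7 ± 1.30), Golm2 (58.5 ± 4.86 against 76.9 ± 5.23) and the actin-capping Capza1 (51.2 ± 2.44 against 65.8 ± 5.84). Litters of the arms did not overlap for any of these genes, which was partly built in by taking them by smallest p.

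For BHB against normal, edgeR called 0 genes, with 2089 at unadjusted p under 0.05 (1201 higher and 888 lower). DESeq2 called 73 (59 higher and 14 lower) and limma voom 0. With the 4 libraries left out edgeR called 5, which were Gm23153, Ccn1, Ildr2, Gm22701 and Cldn4, all but Ildr2 chosen after their values were seen. Single litters carried much of some values: without BHB 1 the log2 differences of Esam, Pdk4, Nupr1, Mt1 and Bdh1 went from 1.92, 1.77, 3.28, 1.665 and 1.01 to 1.08, 0.885, 2.096, 1.05 and 0.62. Without BHB 4 those of C1qb and Slc7a11 went from 4.01 and 2.09 to 2.37 and 1.20. Litters did not overlap for 1526 genes, or 8.62%.

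K was compared with BHB to ask whether both treated arms differed from each other, which is also the test of whether their differences from normal differ. Mitochondrially encoded genes were higher in K than in BHB, and genes of fatty acid and cholesterol synthesis were lower. With an estimated correlation none of these lists was called (adjusted p = 0.304, 0.238 and 0.926). mt-Nd2 was at 1016 ± 40.8 CPM in K and 699 ± 46.2 in BHB (0.54 ± 0.11), and Scd1 at 5.43 ± 2.32 against 13.7 ± 3.33 (-1.34 ± 0.27), with no overlap between litters. Self-renewal genes (camera adjusted p = 0.228) and the marker lists of podocyte (0.39), endothelium (0.389) and leukocytes (0.0998) were not called. No gene passed edgeR's test (smallest adjusted p = 0.403).

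All 13 mitochondrially encoded genes were higher in K (camera adjusted p = 5.25e-09; adjusted p = 0.304 with an estimated correlation), with 0 called over all genes and 5 adjusted over the list alone; fry's mixed test gave an adjusted p of 0.0317. mt-Atp8 was at 231 ± 15.4 against 114 ± 20.3 CPM and mt-Nd6 at 366 ± 41.3 against 226 ± 35.1. Fatty acid synthesis genes were lower (9 of 12, 4 adjusted over the list alone; camera adjusted p = 0.000112; adjusted p = 0.238 with an estimated correlation), and fry called this list (adjusted p = 0.0457). Scd2 was at 574 ± 46.8 against 732 ± 59.4 CPM. Cholesterol synthesis genes (16 of 20 lower, 0 adjusted over the list alone; camera adjusted p = 0.000184; adjusted p = 0.926 with an estimated correlation) included the squalene synthase Fdft1 at 32.5 ± 2.67 against 39.1 ± 3.21 CPM, and the call was lost without K 2 (0.0672). Medians of these lists were 0.46, -0.21 and -0.18, and 0.32, -0.25 and -0.33 without the 4 libraries.

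Insulin and mTOR pathway genes were higher in K than in BHB (20 of 22, 0 adjusted over the list alone; camera adjusted p = 0.000763; adjusted p = 0.304 with an estimated correlation). The insulin receptor Insr was at 165 ± 24.9 against 135 ± 11.6 CPM and the transcription factor Foxo3, which insulin signalling inhibits, at 226 ± 8.29 against 195 ± 19.1. Fatty acid oxidation genes (19 of 20 higher; 0.000763), the tricarboxylic acid cycle (20 of 20; 0.000108), nuclear oxidative phosphorylation (31 of 32; 0.00113), distal tubule (10 of 10; 0.0413) and dissociation stress (13 of 16; 0.00201) were higher by camera, with 0 genes adjusted over the list alone. DNA replication genes were lower (19 of 20, 0 adjusted over the list alone; 0.00176). Each of these 6 lists had adjusted p = 0.926 with an estimated correlation. Cyp4a10 was at 8.50 ± 7.98 against 1.91 ± 0.61 CPM and Cpt1a at 186 ± 87.9 against 111 ± 31.4 (0.75 ± 0.31). Pdha1 and Pdhb, subunits of pyruvate dehydrogenase, were at 182 ± 53.7 and 118 ± 19.7 against 136 ± 16.6 and 96.6 ± 11.1. The replication genes Tk1 and Mcm7 were at 15.4 ± 1.56 and 182 ± 45.2 against 21.2 ± 4.75 and 225 ± 29.9. Without K 3, K 4, BHB 1 and BHB 2 the medians of the fatty acid oxidation, tricarboxylic acid and oxidative phosphorylation lists went from 0.45, 0.28 and 0.19 to -0.03, -0.01 and -0.08, and to 0.25, 0.17 and 0.09 with the covariate. Those of insulin and mTOR, distal tubule, dissociation stress and DNA replication genes went from 0.11, 0.91, 0.25 and -0.15 to 0.15, 0.61, 0.70 and -0.08, and the covariate left the distal median at 0.39. Calls were lost without K 3 for the tricarboxylic acid cycle (0.205), without K 3 or K 4 for fatty acid oxidation (0.224 and 0.0972) and oxidative phosphorylation (0.93 and 0.0972). They were also lost without K 3, K 4 or BHB 4 for DNA replication (0.191, 0.224 and 0.0756), without K 2 or BHB 4 for dissociation stress (0.0905 and 0.205), and without K 3, K 4, BHB 3 or BHB 4 for distal tubule (0.215 to 0.506).

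Single genes with small p that were lower in K than in BHB included the transcription factor Myrf (42.3 ± 2.49 against 57.0 ± 4.05 CPM), the pro-apoptotic Bax (8.90 ± 0.93 against 12.9 ± 1.07) and Dnajb5 (9.66 ± 0.44 against 14.1 ± 1.21). Higher in K were Syt14 (27.3 ± 0.66 against 19.5 ± 1.15) and Fnip1 (82.9 ± 3.70 against 57.3 ± 9.74), and edgeR's adjusted p was 0.53 for each of these genes. Leukocyte genes Lyz2 and S100a9 differed by -2.04 ± 0.76 and -2.33 ± 1.05, and by -0.695 and -0.737 without BHB 4. Of the genes named throughout, Six2 (-0.003 ± 0.228), Lhx1 (0.001 ± 0.246), Eya1 (-0.15 ± 0.19), Wnt4 (-0.16 ± 0.24), Cited1 (-0.28 ± 0.20), Oxct1 (0.21 ± 0.22), Bdh1 (0.17 ± 0.61) and Pdk4 (0.45 ± 0.60) had overlapping litters, with edgeR's adjusted p from 0.752 to 1.

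For K against BHB, edgeR called 0 genes, with 1456 at unadjusted p under 0.05 (658 higher and 798 lower). DESeq2 called 17 (12 higher and 5 lower) and limma voom 0. Without K 3, K 4, BHB 1 and BHB 2 it called 36 (30 higher and 6 lower), and with the marker score as a covariate 1, which was Scd1 (-1.47; adjusted p = 0.00219, against 0.00219 to 0.996 over all alternatives). Litters did not overlap for 719 genes, or 4.06%.

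**Figure D3:**
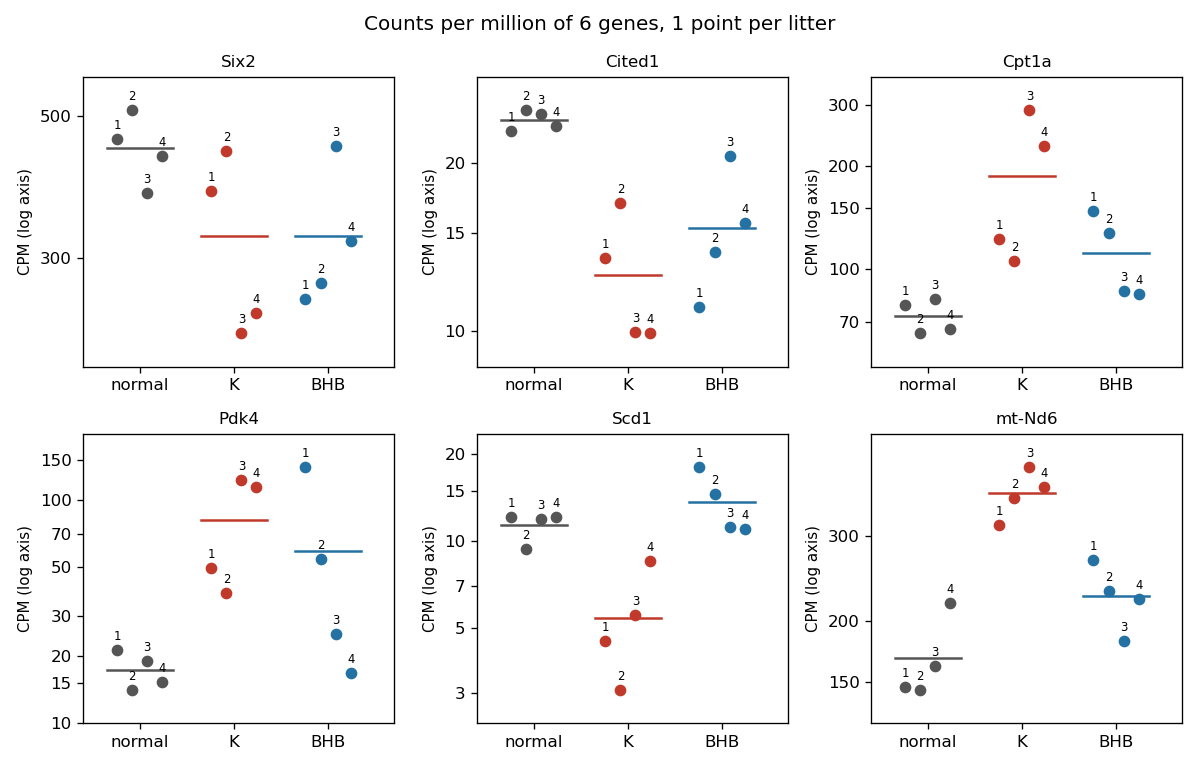
CPM on a log axis of 6 genes in each litter, by arm, with digits for the replicate number and a line for the arithmetic mean of the arm. Six2 averaged 445 in normal, 324 in K and 325 in BHB, and mt-Nd6 averaged 168 in normal, 366 in K and 226 in BHB.

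Both treated arms together were compared with normal, a contrast that does not depend on which label of the treated arms is right. Cited1 averaged 0.58 of its normal level over the treated litters (-0.78 ± 0.17; edgeR adjusted p = 0.252) and was lower in 8 of 8 than in any normal litter. Its difference was -0.51 without K 3, K 4, BHB 1 and BHB 2 and -0.33 with the marker score as a covariate. Cpt1a (0.99 ± 0.28) and G0s2, an inhibitor of fat breakdown (2.012 ± 0.44; 4.54 ± 2.67 and 3.81 ± 1.78 CPM in K and BHB against 1.00 ± 0.30), were higher in every treated litter than in any normal one, as were Entpd1 (2.92 ± 0.49), Dpysl5 (1.02 ± 0.21) and Ildr2 (1.53 ± 0.32). Igdcc3 (-0.84 ± 0.13), Dnah5 (-0.86 ± 0.14) and Ublcp1 (-0.42 ± 0.09) were lower in every treated litter.

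The contrast was 0.78 ± 0.13 for mt-Nd6 and -0.46 ± 0.10 for Dnajb5, whose litters overlapped. Pdk4 (2.00 ± 0.58), Bdh1 (1.09 ± 0.56), Lhx1 (0.70 ± 0.22) and Oxct1 (0.25 ± 0.20) had values above 0, and Six2 (-0.46 ± 0.19), Eya1 (-0.37 ± 0.16) and Wnt4 (-0.19 ± 0.20) below. With the marker score as a covariate Six2 and Eya1 were at 0.11 and 0.07, and Bdh1 and Oxct1 at -0.94 and -0.39. Cpt1a was at 0.07 (edgeR adjusted p = 0.903; 0.44 without the 4 libraries), Pdk4 at 0.26, G0s2 at 1.16, Ildr2 at 0.58, Dpysl5 at 0.64 and Igdcc3 at -0.52. edgeR called 0 genes, with 3331 at unadjusted p under 0.05 (1944 higher and 1387 lower), DESeq2 226 (194 higher and 32 lower) and limma voom 3 (Igdcc3, Dnah5 and Ccm2l, an endothelial gene chosen after its values were seen). It also called 0 without K 3, K 4, BHB 1 and BHB 2. For any difference among the 3 arms edgeR called 0 genes (2510 at unadjusted p under 0.05; smallest adjusted p = 0.314), DESeq2 100, limma voom 4 (Scd1, mt-Nd6, Igdcc3 and Dnah5), and edgeR 32 without those 4 libraries and 1 without normal 4 (mt-Nd6, adjusted p = 0.0424).

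Fold changes of K and of BHB against normal were correlated across genes (Pearson's r = 0.779), and 75.8% of genes had the same sign, though genes are not independent replicates and both sets share the 4 normal litters. Simulated data without an effect gave a mean r of 0.47 (SD 0.301), 10 of 100 sets at or above the observed value, and 66.2% with the same sign. The covariance was 0.146, against 0.0473 (SD 0.0467) in the simulated sets, a difference of 0.0983. With the normal litters split so that each arm had its own 2, r averaged 0.553 over 6 splits (0.429 to 0.617) and the covariance 0.117. DESeq2 called 19 genes higher in both arms and 1 lower, Dnah5. Simulated sets with shared normal litters and no effect had a mean of 2.48 higher and 2.9 lower (median 0 for both), with 2 of 40 sets at or above 19 and 5 of 40 at or above 1. Independent lists would share 0.6 and 0.07, and with the normal litters split, which leaves 2 for each arm, 0 genes were called in both in all 6 splits. Among those higher in both were the endothelial genes Cldn5 and Tek and the leukocyte gene S100a9, of which Tek was chosen after its values were seen.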

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

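All tests of explanations in this part were chosen only after the results they bear on were seen.

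In 14 of 339 groups of 4 litters, 1 litter lay apart from the other 3 by Dixon's ratio of gap to range (critical value 0.829), where chance alone gives about 17. Litter BHB 1 was highest for the stroma list (0.911) and the interferon list (0.918), and lowest for Hoxd11 (0.854). Litter BHB 4 was highest for the leukocyte list (0.858), Lyz2 (0.848) and C1qb (0.95), and lowest for the endoplasmic reticulum chaperone list (0.853) and Ppm1k (0.832). Normal 4 was lowest for Sox13 (0.89), normal 2 for Scd1 (0.927) and normal 1 for Meox1 (0.834), while normal 1 was highest for Foxo3 (0.834). K 1 was highest for Tk1 (0.892) and K 3 for S100a9 (0.969).

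Differences from normal differed between K and BHB by camera for 10 lists. Mitochondrially encoded genes (adjusted p = 5.25e-09), the tricarboxylic acid cycle (0.000108), fatty acid oxidation (0.000763), insulin and mTOR signalling (0.000763), nuclear oxidative phosphorylation (0.00113), dissociation stress (0.00201) and distal tubule (0.0413) were higher in K than in BHB. Fatty acid synthesis (0.000112), cholesterol synthesis (0.000184) and DNA replication (0.00176) were lower. Fry called fatty acid synthesis as well (adjusted p = 0.0457), and with an estimated correlation camera called none of the 36 lists (smallest adjusted p = 0.238).

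Distal tubule, podocyte, ureteric and endothelial marker lists were highest in K 3, K 4, BHB 1 and BHB 2. The leukocyte list was highest in BHB 4 (mean log2 CPM 4.58, against 2.25 in K 4, the next), and the proximal tubule list was lower in BHB 1 (5.36) and BHB 2 (4.57) than in normal 4 (5.77). If these were only nephron-lineage cells further along in development, endothelial markers would have stayed at the normal level, but the endothelial list was higher in K than in normal by 2.017 on the log2 scale (exact p = 0.0286, the smallest that 4 against 4 can give; 0.0935 adjusted over 36 lists), with no overlap between litters (2.32 to 4.153 against 0.769 to 1.679). In BHB the endothelial list overlapped normal (1.125 to 4.696, exact p = 0.0857), with BHB 1 at 4.70, BHB 2 at 3.24 and BHB 4 inside the normal range. By the exact test this argument therefore covers K only. It also assumes that nephron-lineage cells express none of the list's genes, which was not tested. RNA from cells outside the lineage stays open: within arms, the endothelial list followed the tubule and podocyte lists over the 12 libraries (Pearson's r = 0.81, permutation p = 0.0011; Spearman's rho = 0.832, permutation p = 0.0012; both 0.0012 after adjustment), with r = 0.812 without K 2 and normal 2. Distal, podocyte and endothelial lists were already seen to be highest in the same libraries, so this correlation largely restates the pattern. Its permutations also moved deviations between arms, whose spreads differ. An effect of the regimens cannot be told apart from RNA of cells outside the lineage. The marker score was higher in the 8 treated libraries than in the 4 normal ones (exact p = 0.0121, not adjusted), but it was put together from lists already seen to be high in treated libraries, so this restates the pattern. The GFP sort should remove most cells of other types, and whether regimen or dissociation and sorting changed their share cannot be read from these libraries.

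Fatty acid oxidation and PPAR target genes were higher in K. The within-arm slope on the marker score was then removed. The difference of K from the 8 other libraries went from 0.713 (exact p = 0.0606) to 0.117 (exact p = 0.356). The 8 others were not alike after that: BHB differed from normal by -0.368 (exact p = 0.0286). RNA from other cells may account for most of the difference of K from normal. For K against BHB the score removed less. The list's median of 0.453 was 0.249 with the score as a covariate (camera adjusted p = 1.66e-07 at the preset correlation). It was -0.033 without the libraries of highest score (camera adjusted p = 0.508), so the cause of that difference stays open. The slope was fitted once with the real arms and not again for each permutation. Permutation p-values of adjusted scores here therefore leave out its uncertainty and are not strictly exact. An effect of the K regimen on progenitors cannot be told apart from 0 in these values: the adjusted difference from normal was -0.067 (exact p = 0.486). The regimen could also act by changing which cells are present, which was not tested.

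Fatty acid synthesis genes were lower in K. Removing the same slope took the difference from the 8 other libraries from -0.25 (exact p = 0.00606) to -0.308 (exact p = 0.00202, the smallest that 4 against 8 can give; 0.0727 adjusted over 36 lists). Without Scd1 it went from -0.159 to -0.186 (exact p = 0.0101), and for the median of the members from -0.256 to -0.194 (exact p = 0.00606). These differences from the 8 others argue against the mean level of the score as the whole cause, though the p-values leave out the uncertainty of the slope. They cannot do so for each cell type in it. With the same slope removed, the leukocyte and ureteric lists still differed between K and normal by 1.297 and -0.765 (exact p = 0.0286 for each). Against the 8 others they differed by 0.265 and -0.289 (exact p = 0.77 and 0.459). Stroma and erythroid markers are not in the score. RNA from other cells may account for part: with the score as a covariate in the edgeR fit, the median difference from normal went from -0.314 to -0.121 (camera adjusted p = 7.64e-05). The adjusted difference from normal was -0.344 (exact p = 0.0286), and an effect of the K regimen stays open as a hypothesis. Which regimen that was is not settled by the labels, and diet batch or litter differences were not tested.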

How the results depend on the processing

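Leaving out the 4 libraries, the marker covariate, the paired fit of K with normal alone and the exact test of list means were chosen only after seeing the data, and the other settings were fixed before. Genes named were on the same side of the threshold in the same direction in 1115 results over settings other than leaving out a single library, passed it only there in 100 and changed sign in 48. The cause was not tested for any change given here, except that leaving out libraries leaves fewer samples.

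DESeq2 called 276, 73, 17, 226 and 100 genes for K against normal, BHB against normal, K against BHB, both arms against normal and any difference. Limma voom with quality weights called 2 for K against normal, 3 for both arms and 4 for any difference. Without a filter on low counts edgeR called 2, 2, 4 and 5 for K against normal, BHB against normal, both arms and any difference. The count was 0 in all 5 comparisons with RLE factors, upper-quartile scaling and the stricter filter, and in the 3 pairwise comparisons with only the compared arms.

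Between K and BHB, Six2 was at 0.003 with DESeq2 and with RLE factors, 0.255 with voom and 0.024 without a filter, against -0.003 as reported. Voom also gave 0.017 for Eya1, -0.195 for Lhx1, -0.183 for Oxct1 and -0.904 for Bdh1. Lhx1, at 0.001 as reported, was at -0.042 with upper-quartile scaling and -0.005 with only those arms in the model.

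With the replicate block on all 12 libraries, Lhx1 was at -0.002 and Bdh1 at -0.046 between K and BHB. It left 0 genes called in all 5 comparisons (smallest adjusted p 0.323, 0.49, 0.611, 0.326 and 0.464), and all 21, 16 and 10 camera calls kept their side. The replicate numbers do not pair BHB with the other arms: same-numbered libraries had correlations of -0.258 to 0.103 for BHB and normal and -0.441 to -0.216 for K and BHB, and 2 of 12 libraries matched their own number best. For K and normal alone, whose same-numbered libraries deviate together, the replicate block gave 391 genes against 0. All 21 camera calls kept their side there, and of the other lists only stroma changed its side by camera.

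With K 3, K 4, BHB 1 and BHB 2 left out, edgeR called 12 genes for K against normal, 5 for BHB against normal, 36 for K against BHB and 32 for any difference. In K against normal, Oxct1 was at -0.168 and Bdh1 at -0.388, and list medians were -0.71 for proximal tubule, -0.003 for ureteric epithelium, -0.008 for the tricarboxylic acid cycle, -0.058 for nuclear oxidative phosphorylation, -0.007 for oxidative stress and 0.073 for ribosomal proteins. In BHB against normal, Wnt4 was at 0.054, Oxct1 at -0.049, Bdh1 at -0.024, Scd1 at -0.037 and the distal tubule list at -0.217. In K against BHB, Cyp4a10 was at -0.522, Six2 at 0.107, Eya1 at 0.051, Lhx1 at -0.41, Oxct1 at -0.119 and Bdh1 at -0.364. List medians there were -0.033 for fatty acid oxidation, -0.009 for the tricarboxylic acid cycle and -0.082 for nuclear oxidative phosphorylation. For both arms against normal, Oxct1 was at -0.108 and Bdh1 at -0.206. Of the camera calls, 13 of 21, 7 of 16 and 5 of 10 held. Among lists whose median changed sign, camera called nuclear oxidative phosphorylation in K against normal (adjusted p = 0.0121) and in K against BHB (0.00465). It also called ribosomal proteins in K against normal (0.000312).

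With the marker score as a covariate, edgeR called 1 gene for K against normal, 1 for K against BHB and 1 for any difference. The tubule, podocyte, ureteric, endothelial and leukocyte lists form that score, so a fall of those lists here was partly built in. In K against normal, Tmem52b was at -0.099, Pdha1 at -0.029, Idh2 at -0.043, Six2 at 0.138, Eya1 at 0.01, Oxct1 at -0.359 and Bdh1 at -1.093. List medians were 0.043 for self-renewal, -0.83 for proximal tubule, -0.405 for distal tubule, -0.783 for ureteric epithelium, -0.058 for ketone bodies, -0.099 for fatty acid oxidation, -0.138 for the tricarboxylic acid cycle, -0.171 for nuclear oxidative phosphorylation, 0.048 for DNA replication, -0.166 for oxidative stress and 0.166 for ribosomal proteins. All are opposite in sign to the main fit. Camera called the ureteric (adjusted p = 3.75e-05), tricarboxylic acid (0.000286), oxidative phosphorylation (6.45e-06), oxidative stress (0.00835) and ribosomal lists (2.99e-15) there. The others were not called (0.0816 to 0.681). In BHB against normal, Mt1 was at -0.229, Six2 at 0.088, Eya1 at 0.125, Wnt4 at 0.039, Oxct1 at -0.415, Bdh1 at -0.781, Cpt1a at -0.205 and Scd1 at -0.382. List medians were 0.107 for self-renewal, -0.431 for proximal tubule, -0.73 for distal tubule, -0.363 for fatty acid oxidation, -0.28 for nuclear oxidative phosphorylation, 0.184 for DNA replication, -0.095 for oxidative stress and 0.093 for ribosomal proteins. These too are opposite in sign to the main fit. Camera called all of them (adjusted p from 1.32e-12 for oxidative phosphorylation to 0.0174 for self-renewal) except proximal tubule (0.0668) and oxidative stress (0.137). In K against BHB, Six2 was at 0.05, Lhx1 at -0.048 and Bdh1 at -0.312. For both arms against normal, Six2 was at 0.113, Eya1 at 0.068, Oxct1 at -0.387 and Bdh1 at -0.937. Of the camera calls, 4 of 21, 2 of 16 and 10 of 10 held, and none held with an estimated correlation. None passed the exact test of list means after adjustment either, but that test could hardly have kept a call. Its p cannot fall under 0.0286, so an adjusted p of 0.05 needed many lists at that smallest value at once. In K against normal, lists at that value, such as endothelium, had an adjusted p of 0.0935. The exact test therefore decides nothing about the camera calls.

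With each library left out in turn, the count ran from 0 to 1 for K against normal and for any difference, and was 0 otherwise. In BHB against normal Wnt4 ran from -0.279 to 0.027. In K against BHB, Six2 ran from -0.188 to 0.195, Eya1 from -0.315 to 0, Wnt4 from -0.313 to 0.013, Lhx1 from -0.191 to 0.182, Oxct1 from -0.02 to 0.371 and Bdh1 from -0.231 to 0.556. Differences in total counts ran from -864200 to 173000 for K minus normal, -655600 to 925500 for BHB minus normal and -1139000 to 442200 for K minus BHB. Shares differed by -0.0742 to 0.298 percentage points for the 100 most abundant genes and -0.00089 to 0.00366 for haemoglobin (K minus normal), by -0.00509 to 0.1435 for mitochondrial transcripts (BHB minus normal) and by -0.152 to 0.142 for ribosomal proteins (K minus BHB).

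Depth limits genes of few counts most: at 7532784 counts, the smallest library, 1 CPM is about 8 counts, so values such as those of Entpd1 or C1qb in normal rest on a handful of reads.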

Other observations

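Among the tests of other splits, those on counts of genes and on matched libraries were chosen only after the results were seen, and so were the genes named without the 4 libraries and the list tests with the marker slope removed.

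With K 3, K 4, BHB 1 and BHB 2 left out, 2 litters remain in each treated arm, and edgeR's calls are read with that number in mind. Meg3, a maternally expressed imprinted RNA, was higher in K than in normal by 0.86 (adjusted p = 0.019), as were Zdbf2 (0.68; 0.019), Dtna (0.66; 0.019) and the endothelial lectin Clec1a (3.22; 0.019). Between K and BHB, the insulin receptor substrate Irs2 (0.59; 0.0312), the feedback inhibitor of EGF signalling Errfi1 (0.78; 0.0128) and the claudin Cldn4 (1.24; 0.0146) were higher in K. The matricellular gene Ccn1 was lower in BHB than in normal by -0.615 (0.0249) and higher in K than in BHB by 0.82 (0.00663).

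With the within-arm slope on the marker score removed, mitochondrially encoded genes were higher in K than in the 8 other libraries by 0.353 (exact p = 0.00606), and cholesterol synthesis genes lower by -0.208 (exact p = 0.00808). Both had an adjusted p of 0.097 over the 36 lists, and these p-values leave out the uncertainty of the slope.

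Other splits of the same litters were fitted for the counts of genes and lists, and for none of the counts above 0 could chance be excluded. For K against normal, 4 of 35 splits gave at least the real 3502 genes at unadjusted p under 0.05 (highest other 3958), 6 gave at least 21 camera lists (22) and 2 gave at least 1 fry list (1). For BHB against normal, 2 of 35 gave at least 2089 genes at unadjusted p under 0.05 (2118) and 15 gave at least 16 camera lists (22). For K against BHB, 9 of 35 gave at least 1456 at unadjusted p under 0.05 (6121), 30 gave at least 10 camera lists (23) and 4 gave at least 1 fry list (18). For both treated arms against normal, 7 of 100 drawn splits gave at least 3331 at unadjusted p under 0.05 (5610), and for any difference among the arms 11 of 100 gave at least 2510 (5307).

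A real count of 0 is met by every split, so those counts decide nothing about chance. This holds for edgeR's genes past the threshold in K against normal (35 of 35 splits, highest other 87), BHB against normal (35 of 35, 1), K against BHB (35 of 35, 3972), both arms (100 of 100, 1820) and any difference (100 of 100, 1495), and for fry lists in BHB against normal (35 of 35, 1). The split of K 1, K 2, BHB 3 and BHB 4 from the other treated libraries gave those 3972 genes, which points to a structure of the samples that crosses both arms. It is the split by marker score: 3.21 to 3.60 in these libraries, against 4.29 to 5.27 in K 3, K 4, BHB 1 and BHB 2.

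With K and normal paired by replicate number, edgeR called 391 genes. The pairing was read from these same values, and the numbers follow the rank of the marker score in both arms. Only 8 splits part all 4 pairs, too few for a share under 0.05: in the paired fit 1 of 8, the real one, gave as many, and the highest other gave 0. In the fit of all libraries, which ignores the numbers, the same 8 splits gave at most 1556 genes at unadjusted p under 0.05 besides the real 3502. Of the 24 ways to match the 4 K with the 4 normal libraries, 2 had all 4 correlations over 0.1, and the highest count of genes called under another matching was 97 (median 0). By mean correlation, 3 of 24 matchings, the one by number included, were as high. For K and BHB, which the numbers do not pair, 4 of 24 matchings had all correlations over 0.1. By genes at unadjusted p under 0.05 the pairing by number was not the highest: it gave 4087, 2 of 24 matchings, itself included, gave as many, and the others had a median of 2548 and a highest count of 4187.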
